A study of Glycine max with 24 samples.

How the data were processed

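The values were intensities as deposited by the authors, 1 for each probe set and array on a linear scale. The background correction, the summary of probes and the normalization that made them are not given in the sources used here. The columns had medians of 6.421 to 7.151 and a lowest value of 3.22. Whether they had been scaled to each other was not tested, and they were used as deposited after log2 with a floor of 1. The labels describe biotin labelling of RNA from an oligo-dT primer, and every column of the deposited table belonged to 1 of the 24 arrays.

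The groups came from the labels: 2 genotypes, 2 treatments and 2 times, with 3 arrays each. Plants grew in chambers with 16 h of light at 28 °C and 8 h of dark at 20 °C. The labels do not say whether replicates were separate plants, pools or repeated experiments, so the p-values measure only the spread between arrays. Tests used limma 3.58.1 in R 4.3.3. One model held a mean for each of the 8 groups, with 16 residual and 1.13 prior degrees of freedom, and gave 13 comparisons. These were the Mg effect in each genotype and time, its average, its interaction with genotype at each time and with time in each genotype, the genotype difference at each time, and the time difference in each genotype. Genotype differences are PI minus Young and average the treatments, as do time differences, 72 h minus 12 h. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison over the 37593 probe sets whose IDs begin with Gma.

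The 23442 probe sets whose IDs do not begin with Gma, controls aside, served as background. The signal filter, used in the components and as an alternative, was the 95th percentile of their mean values, 2.401 on the log2 scale. The bound of an array was their 99th percentile on it, 2.862 to 3.272. A group lay at background when all its arrays were at or under their bound, and a fold against such a group was computed against the bound and written as at least that size. For genes that passed, log2 differences with any array at background were computed with that array at its bound and written as that value or beyond. Where an array at background could have made a difference smaller, no size was given, apart from fitted values named as such.

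Gene names came from a table for assembly Glycine_max_v4.0, which was used for names only. It paired 8677 probe sets with 1 gene and 370 with several, and 28546 of those tested had no gene in it. The 8677 stood for 6031 genes, 1792 of them with several probe sets, and each gene was represented by the probe set of highest mean. Only 1131 genes had a name.

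Gene lists had been planned as 34 themes. Their members were written down from gene symbols once the name table was at hand and before any test, which gave 39 lists, 37 of them with the 5 or more members that a set test needs. No members were found for magnesium transport, xylem, root hair or root cap. Set tests used camera with a preset correlation of 0.01, and again with the correlation estimated from the arrays. With the preset, 48 list and comparison pairs passed after adjustment within each family of comparisons. With the estimate none did, and 39 of 481 had an unadjusted p under 0.05. Of the 48, 11 were higher and 37 lower. The rotation test fry, which asks for a change in the list itself, gave adjusted p-values of at most 6.67e-04 for the direction of every list called for the Mg effect at 72 h in a genotype. Where fry did not pass for a list that camera called, its value stands beside the list.

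Genes were named by a rule. From each Mg comparison it took the 8 largest rises and falls among named genes that passed and whose arrays did not overlap between groups, a separation that chance gives to 10% of genes with 3 arrays against 3. It took 6 and 6 for genotype and time and 4 and 4 for interactions. From each list it took up to 3 passing members, and all 3 members of the list on Al response. The average added the condition of the same sign in all 4 Mg comparisons, and where no gene passed the rule took the 3 of smallest p. Fewer genes may be printed than the rule took. The planned rule had relied on descriptions, and since none were available a gene name was required in their place.

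The comparisons, the tests, the naming rule in its first form and most alternatives were chosen before the data were examined. The alternatives were the signal filter, all probe sets but controls, quantile normalization, a trend with robust variance, the arrays of a comparison alone, the replicate number as a block, an offset of 32 before log2, and each array left out in turn. A 2-fold limit, equal array medians, the genes of Young at 12 h without 1 array, the bounds and the time differences within treatments were added after the values had been seen.

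Known changes were planted in simulated arrays of the same design to test the procedure. It recovered 24.2% of 66 probe sets changed by 0.5 on the log2 scale, 61.2% of 67 changed by 1 and 83.6% of 67 changed by 2. All of them lay above the signal filter and were changed only in PI with Al plus Mg at 72 h. In the real arrays 12685 probe sets passed in that comparison. The adjustment is less strict where more probe sets change, so these shares do not give the recovery in the real 72 h comparisons. Of 119 calls 6 were false, the shifted list was found, and 0 of 30 unshifted lists were called. Each probe set was simulated independently of the others. The simulation therefore cannot show how the list test behaves when the members of a list vary together.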

Results

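The study measured transcripts in the 1 cm tips of soybean roots (Glycine max) from plants grown in hydroponic culture. The 2 genotypes were the plant introduction PI416937, called PI here, and the cultivar Young. Plants received 10 µM aluminium (Al) either alone or together with magnesium (Mg), and roots were taken after 12 or 72 h. The titles of all arrays with Al alone end in a letter c that the labels do not explain and that raises the question of a control, while their descriptions state treatment with Al only, which was followed here. Each of the 8 groups had 3 replicate arrays, 24 in all. The labels state no Mg dose, and no group without Al was analysed here, so the comparisons show what Mg changed in Al-treated roots and not what Al itself changed. Each array of the Affymetrix soybean type gave 1 intensity for each probe set, and the 37593 probe sets whose IDs begin with Gma were tested. Between 76.8% and 80.5% of these lay above the background of their array, and the number of arrays limits the precision. Arrays of one group correlated at r = 0.981 to 0.994 over the 33039 tested probe sets above a signal filter, and no pair of them was identical.

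Time and Mg divided the arrays more than genotype did. The first principal component held 38.8% of the variance of the 33039 probe sets above a signal filter, and the second held 28.3%. The 6 arrays of roots given Al alone for 72 h lay at 85.67 to 168.1 on the first component. The 6 arrays of roots given Al plus Mg for 72 h lay at 87.41 to 129.8 on the second. All 12 arrays of the 12 h groups lay between −78.14 and −16.83 on the first and between −59.7 and −26.47 on the second, whichever treatment they had received.

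**Figure D1:**
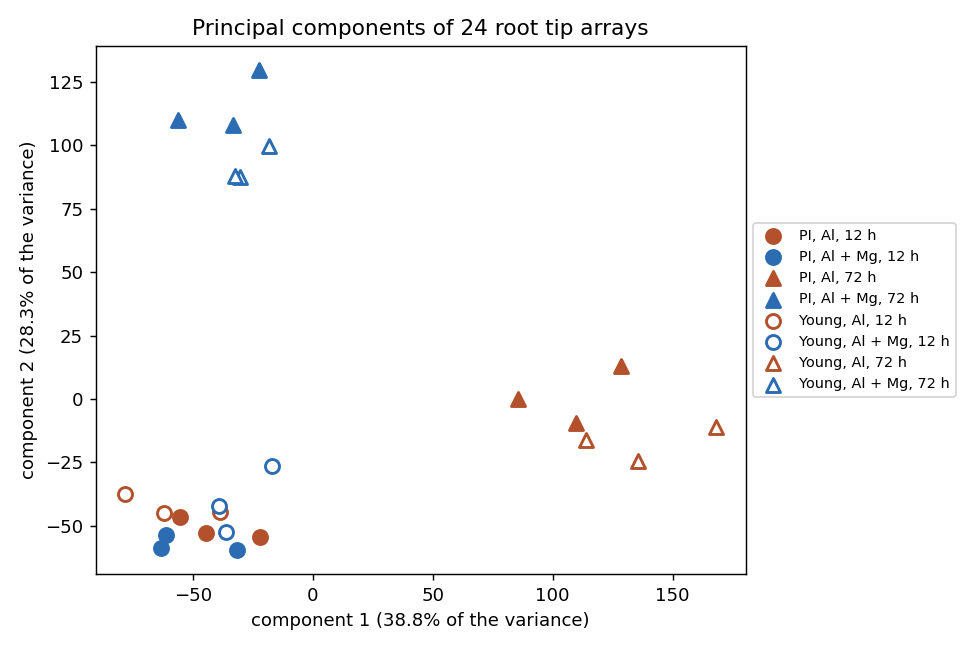
First against second principal component of log2 intensity for the 24 arrays, with the share of variance on each axis; circles are 12 h and triangles 72 h, filled symbols PI and open symbols Young, orange Al alone and blue Al plus Mg. The 72 h arrays of the treatments lie apart, while the 12 h arrays of both treatments lie together.

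The comparison of Al plus Mg with Al alone asks which transcripts follow the addition of Mg, the subject of the series' title. In PI roots at 72 h, transcripts of defence proteins were far lower with Mg. PR-10, a pathogenesis-related protein, had a mean log2 intensity of 14.09 ± 0.35 (SD, n = 3) with Al alone and 2.53 ± 0.21 with Mg, at least 1898-fold lower, since the lower group lay at background (limma, adjusted p = 4.65e-12). PR1-1, another pathogenesis-related protein, was at least 1560-fold lower, and the transcription factor WRKY30 at least 299.1-fold lower. In the defence list 16 of 19 members fell and 1 rose (adjusted over the list alone, 16 and 2), with a median log2 difference of −2.64. Against all other genes the list was lower at camera adjusted p = 4.45e-08, and adjusted p = 0.229 with an estimated correlation.

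NAC and WRKY factors and glutathione transferases fell with these defence transcripts in PI at 72 h. Among NAC factors 14 of 20 fell and none rose, and the same numbers passed when adjusted over the list alone. Their median log2 difference was −1.88 (camera adjusted p = 5.55e-08, adjusted p = 0.267 with an estimated correlation), with NAC6 at −5.76 and NAC12, in part at background with Mg, at −5.41 or lower. Among 53 WRKY factors 29 fell and 5 rose (adjusted over the list alone, 32 and 5), at camera adjusted p = 1.90e-07 and adjusted p = 0.347 with an estimated correlation. WRKY17 had a difference of −7.77 or lower and WRKY53 was at least 127.8-fold lower. Of 37 glutathione transferases, enzymes that join glutathione to reactive compounds, 22 fell and 1 rose, in number the same as when adjusted over the list alone (camera adjusted p = 2.32e-07, adjusted p = 0.229 with an estimated correlation). GSTU43 was at least 22.54-fold lower and GST3 fell by 4.72 on the log2 scale.

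Enzymes of the phenylpropanoid and isoflavonoid pathway were also lower in PI with Mg at 72 h, where 20 of 47 fell and 1 rose (adjusted over the list alone, 22 and 1). The list gave camera adjusted p = 6.92e-05 and adjusted p = 0.313 with an estimated correlation. CYP93A1 and G4DT, which act in the synthesis of the soybean phytoalexin glyceollin, had log2 differences of −6.41 and −5.40, and the isoflavone reductase IFR fell by 4.07. Heat shock proteins and factors followed with 6 of 18 lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.0167, adjusted p = 0.267 with an estimated correlation), led by HSP90A1 at −3.29. All 3 alternative oxidases, mitochondrial enzymes that pass electrons to oxygen without pumping protons, fell: AOX1 by a log2 difference of −5.99 ± 0.67 (SE), AOX2 of −1.55 and AOX3 of −1.17. Calcium signalling genes went both ways, with 4 of 11 higher and 5 lower, among them the calmodulins SCAM-5 at −3.20 and SCAM-4 at −2.48. The ferritin SFERH-2, an iron store, fell by 5.06.

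Other named genes rose in PI with Mg at 72 h. The plasma membrane aquaporin PIP2-1 rose by 1.54 ± 0.21 (SE; limma adjusted p = 2.18e-05), and 7 of 23 aquaporins rose against 1 that fell, NIP1-8, at −5.58 or lower. The gibberellin synthesis enzyme GA20OX3 rose by 1.64 while GA2OX8, which inactivates gibberellin, had a difference of −4.82 or lower. The cell wall loosening expansin EXP1 rose by 1.26, the beta-tubulin TUBB3 by 0.88 and the auxin list's ADR11 by 1.11. Of the 8 auxin genes 4 rose and none fell (adjusted over the list alone, 5 and 0), but the set test did not pass (camera adjusted p = 0.083). GASA peptides, which respond to gibberellin, had 7 of 16 members higher and none lower, and their set test did not pass either (camera adjusted p = 0.244). In all, 7781 probe sets were higher and 4904 lower, 33.74% of those tested, and 993 and 2972 of them differed by at least 2-fold. The 12685 calls became 19811 when probe sets with other prefixes were tested too, and 8007 when the spread came from the 6 arrays compared alone.

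Young roots gave much the same picture at 72 h. PR-10 went from 14.19 ± 0.28 (SD, n = 3) with Al alone to 2.56 ± 0.25 with Mg, at least 2393-fold lower (limma adjusted p = 2.88e-12), and PR1-7 was at least 225.8-fold lower. SABATH2, of a family of methyltransferases, was at least 418.5-fold lower and PSK5 at least 267.1-fold lower. The defence list had 12 of 19 members lower and 2 higher (adjusted over the list alone, 14 and 2), at camera adjusted p = 6.88e-05 and adjusted p = 0.267 with an estimated correlation. NAC factors fell in 17 of 20 cases with none higher, also when adjusted over the list alone (camera adjusted p = 5.55e-08, adjusted p = 0.267 with an estimated correlation), and NAC12 was at least 76.82-fold lower. WRKY factors fell in 32 of 53 cases with 3 higher (adjusted over the list alone, 32 and 4, camera adjusted p = 6.05e-08, adjusted p = 0.313 with an estimated correlation), led by WRKY30 at −8.76, WRKY17 at −7.32 and WRKY53 at −7.04 or lower.

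The other lists that fell in PI fell in Young too. Of 37 glutathione transferases 22 fell and 3 rose (adjusted over the list alone, 23 and 3, camera adjusted p = 7.26e-07, adjusted p = 0.229 with an estimated correlation), and GSTU43 was at least 31.09-fold lower. Of 47 phenylpropanoid and isoflavonoid genes 18 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00705, adjusted p = 0.621 with an estimated correlation), with CYP93A1 at −6.28 and the chalcone synthase CHS1 at −2.99. Heat shock genes had 8 of 18 members lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.0226, adjusted p = 0.267 with an estimated correlation), and the heat shock factor HSF-01 fell by 3.11. AOX1 fell by 8.63 ± 0.67 (SE), AOX2 by a log2 difference of −1.50 and AOX3 of −0.89.

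Auxin genes were higher as a list in Young with Mg at 72 h. Of the 8 auxin genes 5 rose and none fell (adjusted over the list alone, 6 and 0), at camera adjusted p = 0.0499 and adjusted p = 0.267 with an estimated correlation, and the call was lost with the signal filter at 0.0535 and after quantile normalization at 0.0543, in a range of 0.0332 to 0.267 over its alternatives. ADR11 rose by 1.54 and AUX28 by 1.08. Outside this list EXP1 rose by 1.83, TUBB3 by 1.28, the cell cycle gene CCS52 by 1.04, and the catalytic DNA polymerase subunit gene POLD1 by 0.85. GA20OX3 rose by 2.55 ± 0.39 (SE), GASA13 by 2.28 and GASA11 by 1.85, and 9 of 16 GASA peptides rose with none lower (camera adjusted p = 0.0754). PIP2-1 rose by 1.93 and 8 of 23 aquaporins rose against 1 lower, again NIP1-8, at −6.00 or lower. GS-2, of the nitrogen list, rose by 3.54 (adjusted p = 5.5e-07). In all, 8679 probe sets were higher and 6109 lower, 39.34% of those tested, and 2366 and 3360 of these differed by at least 2-fold.

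**Figure D2:**
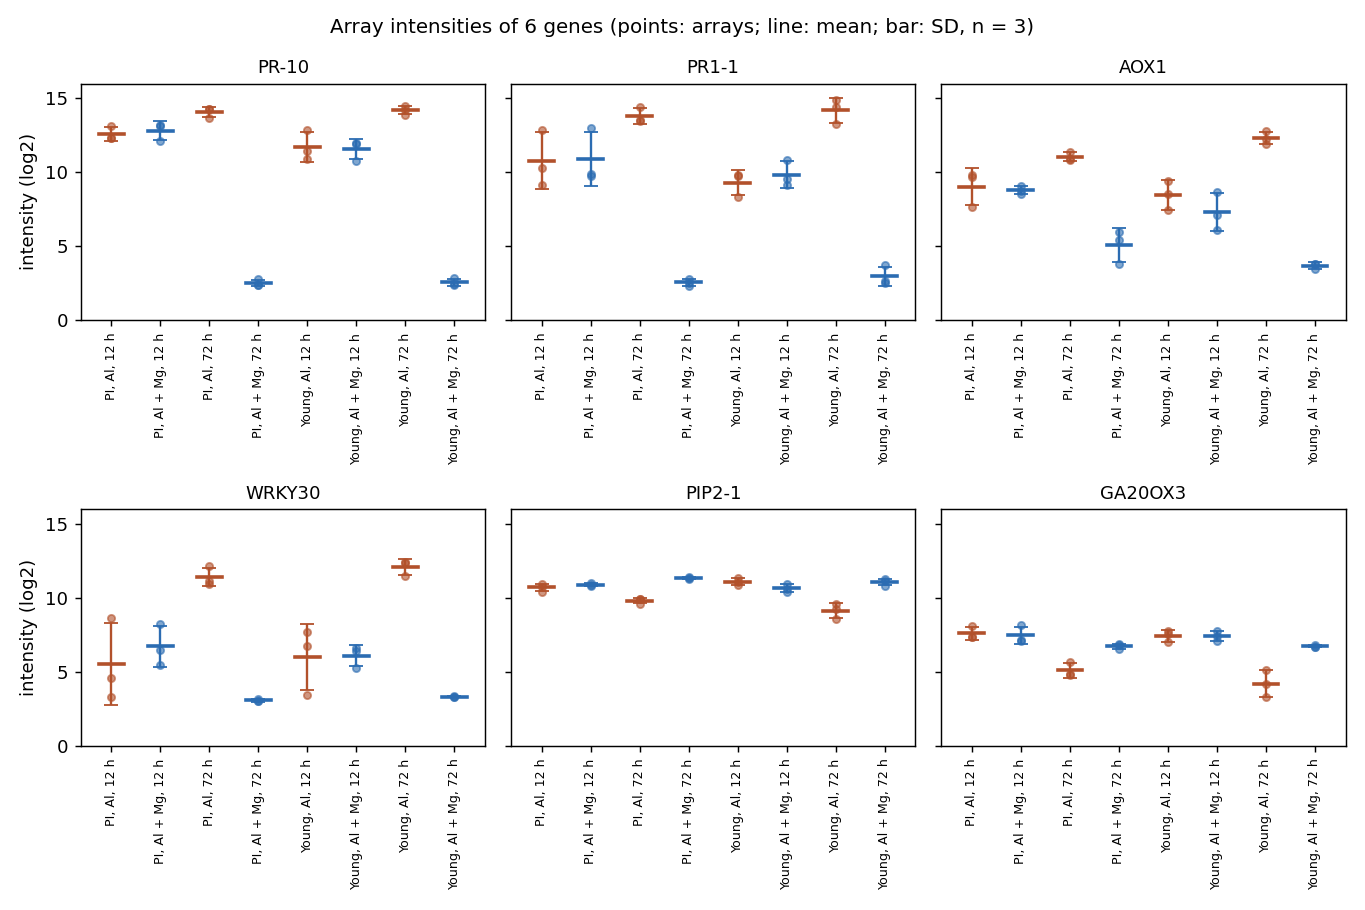
Log2 intensity of PR-10, PR1-1, AOX1, WRKY30, PIP2-1 and GA20OX3 in the 8 groups; points are arrays, lines are means and bars are the SD (n = 3). The means of PR-10 at 72 h are 14.09 and 14.19 with Al alone and 2.53 and 2.56 with Al plus Mg.

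The list of genes tied to Al by name had 3 members, so no set test was made. STOP1, a transcription factor required for tolerance of Al and acid in Arabidopsis, differed with Mg at 72 h by 0.14 in PI (adjusted p = 0.357) and −0.05 in Young (adjusted p = 0.809), and neither passed. FRD3a, named for a citrate transporter, fell by 0.74 in Young (adjusted p = 0.00748) and differed by −0.35 in PI (adjusted p = 0.209). SALI5-4A, named as Al-induced, had a mean log2 intensity of 14.16 with Al alone and 13.5 with Mg in PI at 72 h, and its difference of −0.66 did not pass (adjusted p = 0.255). In Young the difference was −0.63 (adjusted p = 0.267). Organic acid metabolism had 7 of 14 members higher and 1 lower in each genotype (camera adjusted p = 0.258 in PI and 0.292 in Young), and PEPC7, a phosphoenolpyruvate carboxylase, rose by 0.92 in Young.

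**Figure D3:**
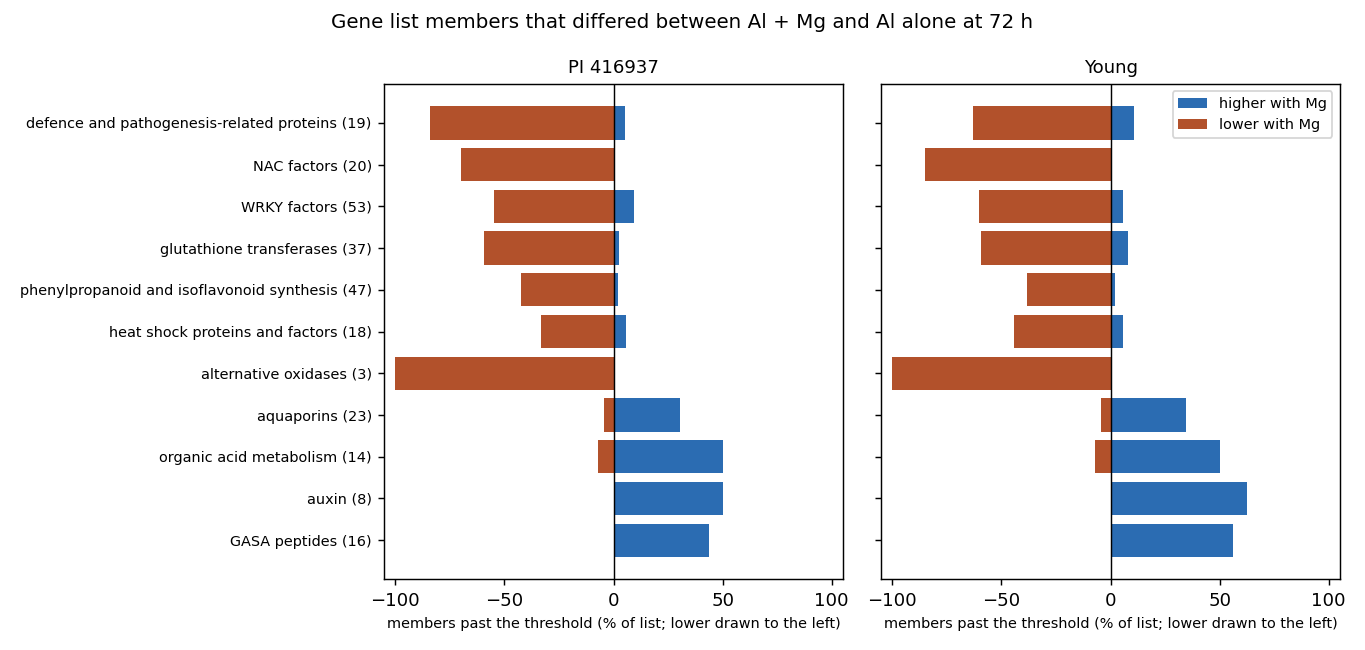
Percent of the members of 11 gene lists that were higher or lower with Al plus Mg than with Al alone at 72 h, in PI and in Young, with the number of members in brackets. Of the NAC factors 14 of 20 fell in PI and 17 of 20 in Young, and none rose in either.

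The responses to Mg at 72 h overlapped in the genotypes: 5360 probe sets were higher in both and 3913 lower in both, where independent lists would share 1796.4 and 796.92, and 41 went opposite ways. Across the tested probe sets, which are not independent replicates, the log2 differences correlated at r = 0.885. Control probe sets at the 3′ and 5′ ends of the same transcripts also differed between the treatments at 72 h. The log2 difference of 3′ over 5′ signal for a cytochrome P450 was 2.51 ± 0.36 (SD, n = 3) with Al alone and 4.12 ± 0.25 with Mg in PI, and 2.26 ± 0.37 and 3.80 ± 0.16 in Young. The 3′ over middle signal differed less, at 1.52 ± 0.12 and 1.73 ± 0.23 in PI and 1.37 ± 0.11 and 1.55 ± 0.08 in Young. For actin 3′ over 5′ was 7.99 ± 0.03 and 8.41 ± 0.17 in PI, and 7.88 ± 0.20 and 8.41 ± 0.04 in Young. Its 3′ over middle was 1.53 and 1.6 in PI and 1.62 and 1.52 in Young.

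At 12 h Mg changed few transcripts that could be told from the spread between arrays. In PI the bZIP list's LOC100127361 was lower with Mg by a log2 difference of −1.20 or beyond, since 1 array lay at background, from 4.69 ± 0.29 to 3.47 ± 0.34 (SD, n = 3; limma adjusted p = 0.00258). It was 1 of 11 probe sets that passed, 4 higher and 7 lower. PR-10, which fell so far at 72 h, differed by 0.23 in PI and −0.18 in Young at 12 h (adjusted p = 1 and 0.934). NAC factors as a list were lower in PI (camera adjusted p = 0.00644, adjusted p = 0.769 with an estimated correlation, fry 0.286) with a median of −0.26, although none passed over all probe sets and 1 when adjusted over the list alone. The PI count was 24 without the first replicate of Al alone and 21 without the first of Al plus Mg, and 0 with limma on the 6 arrays alone, where 2219 probe sets had an unadjusted p under 0.05. Chance alone gives such a p to a share of 0.05 of the 37593 tested, not far below the 2219. In the limma fit of all arrays 1412 had such a p in PI, fewer than chance gives, and 6396 in Young, more than chance gives.

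In Young at 12 h the NAC list went the other way. It was higher with Mg at a median log2 difference of 0.61 (camera adjusted p = 2.52e-04, adjusted p = 0.618 with an estimated correlation), and 10 of 20 members rose when adjusted over the list alone but none over all probe sets. Dehydration and abscisic acid genes were higher too (adjusted over the list alone, 5 and 1 lower, camera adjusted p = 0.0341, adjusted p = 0.577 with an estimated correlation, 0.0523 with the signal filter and from 0.0182 to 0.577 over its alternatives), as were WRKY factors (0.0343, adjusted p = 0.769 with an estimated correlation, 0.0543 after quantile normalization and from 0.0149 to 0.769 over its alternatives) and MYB factors (0.0492, adjusted p = 0.769 with an estimated correlation, 0.0703 after quantile normalization and from 0.0224 to 0.769 over its alternatives). Chaperones of the endoplasmic reticulum were lower (camera adjusted p = 0.0167, adjusted p = 0.769 with an estimated correlation). MYB factors also lost their call with the replicate number as a block (camera adjusted p = 0.0513). Fry did not pass for WRKY factors (0.202), MYB factors (0.095) or the chaperones (0.144). None of these 4 lists had a member past limma's threshold over all probe sets. No gene with a name passed. SAT1 had a log2 difference of 1.31 (adjusted p = 0.0878), and AG1, for which an array of Al alone at background left no measured size, had an adjusted p of 0.0932.

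The Young count at 12 h was 8 higher and 3 lower. Without replicate 3 of Al alone it was 1983 higher and 1134 lower, 3117 in all. It was 232, 35 and 21 without replicates 3, 2 and 1 of Al plus Mg, 7 without replicate 2 of Al alone, and 0 with limma on the 6 arrays compared, where 3775 had an unadjusted p under 0.05. Replicate 3 of Al alone was the array of its group closest to those given Mg, so leaving it out tends to widen the difference between treatments. Without that array NAC factors had 11 of 20 members higher and none lower, at a median of 0.82, and glutathione transferases had 7 of 37 higher and none lower. NAC12 then rose by 3.06 and the sugar transporter SWEET17 by 4.53, while GS-2 fell by 1.46. No probe set passed in both genotypes at 12 h, where independent lists would share fewer than 1, and over all tested probe sets the log2 differences of the genotypes correlated at r = −0.543. In PI only 1412 of the 37593 had an unadjusted limma p under 0.05, fewer than chance alone gives. The PI differences as a whole thus cannot be told from the spread between arrays, and this correlation does not show opposite effects of Mg.

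Averaged over genotypes and times, Mg lowered AOX1 by a log2 difference of −4.01 ± 0.34 (SE), the cytochrome P450 gene CYP82A3 by −4.02, and GSTU41 by −2.14, each with the same sign in all 4 comparisons. For genes named from the largest averages that sign was a condition of the naming rule. Without replicate 3 of Al alone the Young difference at 12 h was 0.017 for CYP82A3 and −0.673 for AOX1. The average mainly carries the 72 h response, since 11 probe sets passed in each genotype at 12 h, against 12685 and 14788 at 72 h. The NAC list, lower in the average, was higher with Mg in Young at 12 h. Of the genes of the same sign throughout, H1 rose by 1.06 and GASA13 by 0.98. The lists lowered were NAC factors (16 of 20 lower and none higher, the same adjusted over the list alone, camera adjusted p = 5.55e-08), WRKY factors (27 of 53 and 3, adjusted over the list alone 32 and 5, camera adjusted p = 6.65e-08), glutathione transferases (21 of 37 and 3, adjusted over the list alone 22 and 3, camera adjusted p = 3.94e-07) and defence (13 of 19 and 0, adjusted over the list alone 14 and 1, camera adjusted p = 6.84e-07). Phenylpropanoid genes (17 of 47 and 0, adjusted over the list alone 17 and 1, camera adjusted p = 0.00142) and heat shock genes (8 of 18 and 0 both ways, camera adjusted p = 0.00705) were lower too. Auxin genes were higher (4 of 8 and none lower, adjusted over the list alone 7 and 0, camera adjusted p = 0.0449, 0.0501 with the signal filter and from 0.031 to 0.267 over its alternatives). With an estimated correlation the adjusted p of these 7 lists lay between 0.229 and 0.528. In all, 7221 probe sets were higher and 4957 lower, of which 103 and 1437 differed by at least 2-fold.

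Whether Mg acted differently over time was tested within each genotype. In PI the Mg effect was lower at 72 h than at 12 h for PR-10, PR1-1 and WRKY30 (limma adjusted p = 1.13e-09, 7.92e-06 and 4.24e-04). Their 72 h group with Mg lay at background, so the log2 differences were −11.12, −10.72 and −9.44 or lower. BBI-2, a protease inhibitor of the Bowman-Birk type, went the other way by 2.89. Defence genes had 11 of 19 lower values of this difference and none higher (adjusted over the list alone, 16 and 0, camera adjusted p = 2.97e-09, adjusted p = 0.185 with an estimated correlation). Glutathione transferases (14 of 37 lower, adjusted over the list alone 15, camera adjusted p = 4.97e-07) and NAC factors (10 of 20, adjusted over the list alone 11, camera adjusted p = 4.04e-06) had none higher. WRKY factors (17 of 53 lower and 4 higher, adjusted over the list alone 25 and 6, camera adjusted p = 2.47e-06) and phenylpropanoid genes (13 of 47 and 0, adjusted over the list alone 16 and 0, camera adjusted p = 1.09e-05) followed. With an estimated correlation these 4 had an adjusted p between 0.358 and 0.452. In all, 3502 probe sets had a higher and 3019 a lower Mg effect at 72 h, while of the 3234 that differed by at least 2-fold 882 were higher and 2352 lower.

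In Young the same test gave, with arrays of the 72 h Mg group at background, PR1-1 at −11.48 or lower and PR-10 at −11.05 or lower, against GS-2 at 4.55 and the polygalacturonase PG7 at 3.00. NAC factors had 18 of 20 lower and none higher (adjusted over the list alone, 19 and 0, camera adjusted p = 1.2e-08, adjusted p = 0.41 with an estimated correlation). WRKY factors (30 of 53 lower and 2 higher, adjusted over the list alone 32 and 2, 4.92e-08, adjusted p = 0.42 with an estimated correlation), glutathione transferases (21 of 37 and 0, adjusted over the list alone 23 and 0, 2.75e-06, adjusted p = 0.375 with an estimated correlation) and defence genes (12 of 19 and 2 both ways, 2.02e-04, adjusted p = 0.41 with an estimated correlation) were lower. Phenylpropanoid genes passed at 0.0487 (12 of 47 lower and 1 higher, adjusted over the list alone, 11 and 1, adjusted p = 0.693 with an estimated correlation) but not with the mean of all probe sets of a gene, at 0.072 in a range of 0.0257 to 0.693 over its alternatives. Chaperones of the endoplasmic reticulum had 6 of 8 members higher and none lower (adjusted over the list alone, 8 and 0, camera adjusted p = 0.0403, adjusted p = 0.693 with an estimated correlation), PDIL-2 among them at 0.98. In all, 7570 probe sets were higher and 5647 lower, while of the 7319 that differed by at least 2-fold 3276 were higher and 4043 lower.

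The responses of the genotypes to Mg were compared directly. At 72 h SABATH2 differed (limma adjusted p = 1.56e-05), with a mean of 11.68 with Al alone and 2.48 with Mg in Young, and of 3.84 and 2.50 in PI. WRKY40 also differed (adjusted p = 2.13e-06), at 4.50 with Al alone in Young and at background in the other 72 h groups. KR3 differed too (adjusted p = 0.00594), with 8.08 and 6.36 in Young and at or near background in PI. For these 3 the arrays at background leave the size of the difference unmeasured. PIB1 and SLR1 differed by −1.03 and −0.79. Cell wall genes responded lower in PI (camera adjusted p = 0.0278, adjusted p = 0.394 with an estimated correlation), with 0 higher and 1 lower of 17 (adjusted over the list alone, 1 and 5). Chaperones of the endoplasmic reticulum did so too (0.04, adjusted p = 0.693 with an estimated correlation, fry 0.179), with none of 8 passing and 1 lower when adjusted over the list alone. LEA and seed maturation proteins responded higher in PI (0.0476, adjusted p = 0.42 with an estimated correlation), with 1 of 29 higher and none lower (adjusted over the list alone, 2 and 0), but not after quantile normalization, at 0.137 in a range of 0.0206 to 0.42 over its alternatives. Of 544 probe sets that passed, 302 were higher and 242 lower. The count was 301 without replicate 2 of Young with Al plus Mg, 321 at 2-fold or more, and 221 with limma on the 12 arrays alone.

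At 12 h the NAC list differed between the genotypes' responses, lower in PI than in Young at a median log2 difference of −0.95 (camera adjusted p = 1.39e-04, adjusted p = 0.554 with an estimated correlation). None of its members passed over all probe sets, and 11 of 20 did when adjusted over the list alone. Chaperones of the endoplasmic reticulum went the other way (camera adjusted p = 0.0253, adjusted p = 0.693 with an estimated correlation, fry 0.174, and none passed in either adjustment). No gene with a name passed. LOC100127361, with an array of PI with Mg at background, had a log2 difference of −1.32 (limma adjusted p = 0.0572) and ICL1 of −3.29 (adjusted p = 0.0731). WRKY15, for which 6 of its 12 arrays at background left no measured size, also had an adjusted p of 0.0731. With limma 5 probe sets passed, 2 higher and 3 lower, against 6236 at an unadjusted p under 0.05. Without replicate 3 of Young with Al alone 2614 passed, without replicates 3, 1 and 2 of Young with Al plus Mg 534, 17 and 8, without replicate 1 of PI with Al alone 13, without replicate 2 of PI with Al plus Mg 10, and without replicate 2 of Young with Al alone 3.

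The genotypes were compared at each time as the mean of both treatments, and no difference within a treatment was tested. At 12 h the superoxide dismutase gene SODB2 was higher in PI by a log2 difference of 3.06 ± 0.39 (SE; limma adjusted p = 5.00e-05). The transcription factor BZIP94 and the sieve element protein SEOM lay at background in Young and were higher in PI by at least 3.63 and 2.66, and in each of these Young had the lower value on every array. KR3, at background in PI, had a difference of −2.82 or lower, the seed maturation protein PM16 of −2.45, and GOLS, named for galactinol synthase, of −2.25. Aquaporins had 11 of 23 members lower in PI and 1 higher (adjusted over the list alone, 12 and 1, camera adjusted p = 9.37e-05, adjusted p = 0.531 with an estimated correlation), with PIP1-1 at −1.58 and PIP1-8 at −0.91. MYB factors had 14 of 69 lower and 1 higher (adjusted over the list alone, 15 and 2, camera adjusted p = 0.0411, adjusted p = 0.983 with an estimated correlation), MYB60 among them at −1.71 or lower, since arrays of PI lay at background. The MYB call was lost with the replicate number as a block (camera adjusted p = 0.0542). FRD3a was lower in PI by a difference of −0.73 (adjusted p = 0.00233). In all, 2369 probe sets were higher and 2503 lower in PI, and 441 and 573 of these differed by at least 2-fold.

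At 72 h SODB2 was higher in PI by 3.80 and SODB by 3.16, and BZIP94, at background in Young, by at least 4.12. KR3, PM16 and the acid phosphatase PAP25, each with PI arrays at background, had differences of −4.08, −3.45 and −2.35 or lower. Green tissue markers had 6 of 14 members higher in PI and none lower (adjusted over the list alone, 7 and 0, camera adjusted p = 0.0321, adjusted p = 0.983 with an estimated correlation), among them CAB3, a chlorophyll-binding protein, at 1.57. Glutathione transferases had 7 of 37 lower and 2 higher (adjusted over the list alone, 8 and 2, camera adjusted p = 0.0321, adjusted p = 0.983 with an estimated correlation), with GSTU28 at −1.79. WRKY factors had 8 of 53 lower and none higher (adjusted over the list alone, 7 and 0, camera adjusted p = 0.0411, adjusted p = 0.983 with an estimated correlation, fry 0.0805). The WRKY call was lost with the replicate number as a block (camera adjusted p = 0.0542). In all, 3612 probe sets were higher and 3534 lower, 476 and 733 of them by at least 2-fold. Of the calls at 12 h, 1071 were higher and 1217 lower in PI at 72 h as well, where independent lists would share 227.62 and 235.3, and 58 went the opposite way.

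The times were compared within each genotype as the mean of both treatments. If treatment began at the same hour for all plants, 12 and 72 h fell at different points of the light and dark cycle. Differences between the times, here and within a treatment, then cannot be told from differences by time of day. In PI this mean rose from 12 to 72 h for CAB3 by 4.22 ± 0.25 (SE; limma adjusted p = 1.8e-09), for PPCK1, a kinase of phosphoenolpyruvate carboxylase, by 3.60, and for the polygalacturonase inhibitor PGIP4, at background at 12 h, by at least 3.36. One other probe set of CAB3 was called in the opposite direction. IFR fell by 3.36, PM16, at background in PI with Mg at 72 h, had a difference of −3.27 or lower, and the clock gene LHY fell by 1.69. In Young CRK39, a receptor-like kinase, rose by 4.12 and PGIP4 by at least 2.64, while the nitrate transporter NRT2 fell by 3.98, the lipoxygenase LOX9 fell by 2.93 and LHY fell by 2.37. WRKY factors were higher at 72 h in Young (29 of 53 higher and 7 lower, adjusted over the list alone 31 and 7, camera adjusted p = 0.0019, adjusted p = 0.904 with an estimated correlation), and no list passed in PI. This rise in Young was that of Al alone, where 37 rose and 4 fell, while 2 rose and 7 fell with Al plus Mg. The counts were 8718 higher and 10387 lower in PI, and 8155 and 9937 in Young. At 2-fold or more they were 2374 higher and 2254 lower in PI and 2427 and 1646 in Young. In PI the higher calls were also the more numerous with equal array medians, 10534 and 9572, and with all probe sets but controls, 11146 and 9923.

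Several lists had more members higher than lower over time with Al alone, and fewer higher than lower with Mg. No list was tested as a set within a treatment, so these are counts of single probe sets. With Al alone, NAC factors rose between 12 and 72 h in 10 of 20 cases in PI, with 1 lower, and in 18 of 20 in Young, with none lower. With Al plus Mg, 1 of 20 rose and 6 fell in PI, and 1 rose and 9 fell in Young. Defence genes rose in 9 of 19 cases and fell in none in PI with Al alone, and rose in none and fell in 11 with Al plus Mg. In Young 12 rose and 3 fell with Al alone, and none rose and 9 fell with Al plus Mg. Of 53 WRKY factors in PI 29 were higher and 6 lower under Al alone, and 8 and 15 with Mg, at a median log2 difference of −0.06. Within Al alone 5900 probe sets rose and 8844 fell in PI, and 7788 and 10890 in Young, but by at least 2-fold 2944 rose and 2098 fell in PI and 4327 and 3447 in Young. Within Al plus Mg 8154 rose and 8430 fell in PI, and 5824 and 5877 in Young, and by at least 2-fold 2667 and 3154 in PI and 1765 and 2105 in Young.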

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

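Every test of an explanation below was chosen after the result it concerns had been seen, while the interaction tests were planned. The differences between the genotypes' responses to Mg covered 5 probe sets at 12 h and 544 at 72 h. The differences between the times covered 6521 in PI and 13217 in Young. The named genes were ranked by the fitted log2 difference between the genotypes' responses at 72 h, with no array set to its bound. The highest were SABATH2 at 7.85, WRKY63 at 3.24, KR3 at 2.28 and WRKY40 at 2.13. On the negative side were WRKY32 at −1.19, PIB1 at −1.03, SLR1 at −0.79 and BZIP110 at −0.75. Arrays at background leave no bound for the sizes of SABATH2, WRKY63, KR3 and WRKY40. Their fitted values are therefore not measured sizes, and their ranks are uncertain. The call of SABATH2, KR3, WRKY40, PIB1 and SLR1 held whichever of the 12 arrays was left out. WRKY63 lost its call without replicate 2 of Al alone in Young (adjusted p = 0.118), WRKY32 without replicate 2 of Al plus Mg in Young (adjusted p = 0.111) and BZIP110 without replicate 2 of Al alone in Young (adjusted p = 0.0983), and each lost it without most of the other arrays too.

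Probe sets whose IDs do not begin with Gma were left out of the tests, yet 14241 of 23442 passed for the Mg effect in PI at 72 h, 14199 of them higher. In Young 18 passed, 7 higher and 11 lower. The median difference was 0.0111 in PI and 0.00371 in Young on the log2 scale, and in PI 6 were higher and 22 lower by at least 2-fold. Their median log2 value was 2.1493 to 2.1521 on the PI arrays of Al alone at 72 h and 2.1608 to 2.1666 on those with Mg. The background of these Mg arrays thus lay slightly higher as a group. Whether this came from the arrays or from the treatment cannot be told here. How much it added to the rises of tested probe sets in PI was not tested.

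The falls with Mg at 72 h in both genotypes came with a larger 3′ over 5′ signal of control transcripts, while their 3′ over middle signal moved little or both ways (P450 1.52 to 1.73 in PI and actin 1.62 to 1.52 in Young). Loss of the 5′ ends of transcripts in the RNA of Al plus Mg roots may have added to them. Other probe sets of the same genes also fell in 78.8% of cases in PI and 79.9% in Young. Their places along the transcripts were not used, so these shares cannot tell how much such a loss added. Harvest at another time of day was tested with LHY, which differed by no more than 0.0968 between treatments at 72 h, against −1.69 and −2.37 between the times. Scaling of the arrays to each other left at least 90.8% of the number of probe sets 2-fold lower after quantile normalization. No biological explanation was tested.

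Replicate 3 of Al alone in Young at 12 h correlated better with the arrays given Mg (mean r = 0.9912) than with its own group (0.9818). A swap with an array of the Al plus Mg group was tested, and 0 of the 3 stood closer to the remaining Al arrays than to each other. A single wrong label or handling of that array could not be told from a root sample that differed, and without it 3117 probe sets passed against 11 with it. The array was kept in every result unless the text says otherwise.

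Genotype differences of 2- to 4-fold may in part come from probe sequences that match one genotype better. Other probe sets of the same genes were called in the same direction in 51.1% of cases at 12 h and 59.7% at 72 h. For Mg differences of 2- to 4-fold, taken at 72 h only, the shares were 72.8% in PI and 75.3% in Young. The larger Fisher exact p of genotype against Mg was 0.0186. Above 4-fold 12 of 20 other probe sets followed at 12 h and 82.1% of 28 at 72 h. For Mg at 72 h the shares were 81.8% in PI and 84.1% in Young, so the lower share did not extend to the larger genotype differences at 72 h. Over all genotype differences of at least 2-fold they were 53.7% at 12 h and 66.3% at 72 h, against 76.9% in PI and 79.0% in Young for Mg at 72 h. Probe sets of one gene are not independent, so the p is rough.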

How the results depend on the processing

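The 2-fold limit and equal array medians were chosen only after the results had been seen, and the other settings were planned. No called gene list and no named gene turned its direction under the settings run on it. Where a count moved, the cause was not tested, apart from the 2-fold limit, which can only lower a count.

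In PI at 12 h the 11 calls of the Mg effect became 5 with the replicate block, 0 with only the arrays of the groups compared (limma, 2219 at an unadjusted p under 0.05), 6 at 2-fold, and 11 to 24 with single arrays left out. Equal medians gave 5 higher and 5 lower and all probe sets 5 and 4 (55.6% higher), against 4 and 7 (36.4% higher). In Young at 12 h the 11 became 5 with the signal filter, 17 with trend and robust variance, 6 with the replicate block, 6 with the offset of 32, 0 with only the arrays compared (limma, 3775 at an unadjusted p under 0.05), 5 at 2-fold, and 7 to 3117 with single arrays left out, the highest without replicate 3 of Al alone.

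At 72 h the 12685 calls in PI became 19811 with all probe sets but controls (75.4% against 61.3% higher), 8007 with only the arrays compared, 3965 at 2-fold, and 10549 to 11698 with single arrays left out. The 14788 in Young became 5726 at 2-fold and 12176 to 14241 with single arrays left out, and the 12178 of the average became 1540 and 11357 to 12235.

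The interaction of Mg and genotype at 12 h, 5 calls, became 3 with all probe sets, 8 after quantile normalization (5 higher and 3 lower, against 2 and 3), 3 with the replicate block, 3 with the offset of 32, 2 at 2-fold, and 3 to 2614 with single arrays left out, the highest without replicate 3 of Al alone in Young. Equal medians gave 1 higher and 3 lower. At 72 h the 544 became 221 with only the arrays compared, 321 at 2-fold, and 301 to 673 with single arrays left out, the lowest without replicate 2 of Al plus Mg in Young.

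The interaction of Mg and time went from 6521 to 3234 at 2-fold in PI and from 13217 to 7319 in Young, with 5078 to 6436 and 11017 to 14257 when single arrays were left out. Genotype differences went from 4872 to 1014 at 12 h and from 7146 to 1209 at 72 h at 2-fold, with 3651 to 4946 and 5402 to 6830. All probe sets gave 6155 higher and 3272 lower at 72 h, 65.3% against 50.5% higher. Time differences went from 19105 to 4628 in PI and from 18092 to 4073 in Young at 2-fold, with 17479 to 18800 and 16416 to 18206.

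The 48 gene list calls became 51 with the filter, 46 after quantile normalization, 45 with the replicate block, 54 with the mean of all probe sets of a gene, and 0 with an estimated correlation (limma's camera, 39 of 481 at an unadjusted p under 0.05). All probe sets but controls was not run for gene lists, since every probe set with 1 gene begins with Gma. Of 952 calls of named genes, 942 held with the filter, 933 after quantile normalization, 915 with the replicate block, and 789 whichever array was left out. The replicate numbers did not pair the arrays: 8 of 24 correlated best with their own number, and the 12 pairs of treatments had r from −0.348 to 0.41 with a median of −0.116.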

Other observations

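The tests of chance by splitting the arrays, and the comparison of the Young response at 12 h without 1 array with that at 72 h, were chosen only after the results had been seen. Single members of lists not described so far were called for the Mg effect at 72 h, while no camera test of these lists passed. Receptor-like kinases went both ways, with 7 of 18 higher and 5 lower in PI and 7 and 6 in Young, and among them CRK39 fell by 5.98 in PI and fell by 4.21 in Young. Phosphate genes had 7 of 19 higher and 3 lower in each genotype. Bowman-Birk protease inhibitors parted, since BBI-1 fell by 2.75 in PI and fell by 3.67 in Young while BBI-2 rose by 1.99 and 1.29. Of the sugar transporters SWEET29 fell by 3.09 in PI and fell by 4.13 in Young.

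The response of Young at 12 h without replicate 3 of Al alone ran against the response at 72 h. Of its 3117 calls 189 were higher and 21 lower at both times, where independent lists would share 457.81 and 184.28, and 1381 went opposite ways (r = −0.305). The array left out had been picked because it stood with the arrays given Mg. Its removal tends to widen the difference between treatments at 12 h and to raise this count. NAC factors, lower at 72 h, were higher at 12 h at a median of 0.61 with all arrays and of 0.82 without that one. Whether the array was wrongly labelled or handled was left open. The 11 calls made with all arrays were themselves not stable. They became 0 with limma on only the arrays compared, where 3775 probe sets had an unadjusted p under 0.05.

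For single comparisons of Mg the arrays allow 10 splits, too few for a share under 0.05. In PI 3 of 10 splits gave at least the real 11 calls at 12 h (highest other 14) and 1 of 10 the 12685 at 72 h (highest other 28). In Young 3 of 10 gave at least the real 11 at 12 h, with 509 for the split that put replicate 3 of Al alone with replicates 1 and 3 of Al plus Mg, and 1 of 10 the 14788 at 72 h (highest other 9). The 509, many times the real count, point to a structure of these 6 arrays in which that replicate stands with arrays given Mg, and whether its label is right was not settled.

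For the other comparisons 100 splits each were drawn. For the average of Mg 2 of 100 gave at least the real 12178, the highest other 14248, and for the interaction with genotype at 12 h 3 of 100 gave at least the real 5, the highest other 319. The 319, many times the real count, again point to a structure of the samples. In both, less than 5% of the splits reached the real count, but a split other than the real one called more. A split that mixes groups that differ adds their difference to the spread of the fit, which lowers its own count. For the average the other splits had a median of 0, so its low share adds little beyond the differences at 72 h. For the interaction the share rests on 5 calls, which became 3 to 2614 with single arrays left out, so no conclusion was drawn from it. For the remaining comparisons only the real grouping reached its own count. That share is the lowest that 100 splits can give. Here too a mixed split adds group differences to the spread, so the share speaks only weakly against chance and does not exclude it. For the interaction with genotype at 72 h 1 of 100 reached the real 544 (highest other 24), for that with time 1 of 100 reached 6521 in PI (1090) and 1 of 100 reached 13217 in Young (10738). For genotype 1 of 100 reached 4872 at 12 h (3274) and 1 of 100 reached 7146 at 72 h (1670), and for time 1 of 100 reached 19105 in PI (11713) and 1 of 100 reached 18092 in Young (14365).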
